A study of soil metagenome with 18 samples.

How the data were processed

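Soil metagenomic DNA was measured in 18 libraries of 6 groups with 3 replicates each. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total DNA was extracted from soil with a commercial kit and Illumina libraries were made from it. The assembly, gene catalogue, mapping and counting steps and their software are not given in the sources used here. The deposited values are 1 table with a score per gene and library, whose columns match the library codes in the labels, and 0 columns were left unmapped. It lists 18646664 genes by number, up to number 20591824, so 1945160 numbers below the highest are not listed.

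The unit of the deposited score was worked out from the values, since no header or label states it. Scores are whole numbers of 0 or more with a smallest positive value of 1, and library totals ran from 35.0 to 56.7 M, a ratio of 1.62. They are not read counts: many genes take only multiples of their own step. Of 8000 genes drawn from those with a smallest positive value of 4 to 6, at least 9 libraries above 0 and a highest value of 14 to 99, 1056 were explained by 1 step in all libraries, within rounding to whole numbers, and 0 were after shuffling genes within each library. When the step was taken from 17 libraries, 95.6% to 99.0% of the values of the remaining library were whole multiples of it. The match was 20.7% to 29.0% for a step 0.9 times as large, 46.7% to 60.8% for 0.95 times, 52.6% to 72.1% for a step larger by 0.05 of its size and 28.3% to 47.8% for 1.1 times. No library matched a changed step better, so no rescaling of the authors' score between libraries by such factors was seen. Such steps would arise if read numbers were divided by gene length and rounded, but the authors' formula is not given in the sources used here. Rounding means that a gene listed at 0 can have had a read. No interval for counting error was computed, since the number of reads is unknown, and library totals are given as the measure of depth.

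Each score was multiplied by the mean library total, 45.3 M, over its own library total. The plan fixed before the data were examined had named limma on log2 values without scaling for units other than counts. The scaling departs from it and was chosen after the totals had been seen and before any comparison was fitted, and the fit without scaling was kept as an alternative. A count model had been planned for read counts and was not used. Genes with a mean scaled score of at least 5 over all 18 libraries were tested, a limit also set after the table had been seen. These were 2070450 genes, 11.1% of those listed, and they held 43.2% to 52.5% of the library totals. Tests were run on log2(scaled score + 1) with limma's moderated test with a trend, in 1 fit of the 6 groups, and p-values were adjusted by Benjamini-Hochberg within each of 11 comparisons at a threshold of 0.05. Log2 changes are on this scale, which understates the change of genes with low scores, and no log2 change is given for a single comparison against a group listed at 0 throughout, except for the batch gene fitted with a batch term. Differences between changes that involve such groups are fitted values and no bound. Genes with nearby numbers rose and fell together, with a median correlation of 0.558 between neighbours and 0.00434 at a distance of 100, so genes are not independent.

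The fit was written in closed form for speed and checked against limma on 50000 genes, where the largest difference in p was 1.42e-14. It was tested on simulated data for the comparison of decaying root in wheat, with 200 genes changed, a dispersion of 0.02 and gene steps from 0.3 to 2.5, set so that the residual spread (SD, log2) of 0.556, 0.548 and 0.567 at the 3 sizes was near the real 0.569. Earlier simulations with other step ranges were replaced for this reason. Among 50000 genes the test recovered 12.0% of genes changed 4-fold and 0% of those changed 2-fold, 1.5-fold or 0.5-fold, and it called 0 unchanged genes. Among 2000 genes it recovered 76.0%, 2.00%, 0% and 0%, and among 540 genes 84.0%, 34.0%, 10.0% and 16.0% in the same order. It called 1 unchanged gene and 5 unchanged genes (1.47%) there. The 540-gene size, where the share of changed genes is near the real one, was added after the low recoveries at the larger sizes had been seen. Small changes are therefore often missed at this depth and replication, and so are 4-fold changes where few genes change.

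Genes named in the text follow a rule fixed before the data were examined. Among genes past the threshold, with at least the median mean score of the tested genes and with libraries of both groups not overlapping (not required for the interaction), the 10 with the largest rise and the 10 with the largest fall were taken per comparison. That rule would have skipped genes without a usable name. The files pair no gene number with a name, so this part was dropped and at most the first 2 of each direction are printed by number. Gene lists by function and organism had been fixed as well, and they and the planned genus level were not analysed here because there are no names to match.

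Bray-Curtis distances were computed over all listed genes on relative abundances. The share of squared distances per factor was computed as in vegan's adonis2, from which it differed by at most 1.7e-16, with 99999 permutations for group. The other community tests enumerated all 400 relabelings of decaying root, or of crop, within the other factor. Those on shares of squared distances count labelings with an F at least as high, and those on distances and richness are two-sided. Richness was the number of genes above 0, and diversity the Shannon index in natural log units. In a thinned copy of the table each score unit was kept with a probability equal to the lowest library total over the library's own, drawn once with a fixed seed. Score units are not reads, so thinning only approximates equal depth.

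A gene was said to split the libraries cleanly when it was at 20 or more in every library of one side and at most 0.1 times that side's lowest score in the other. The split that cut across groups, had 5 to 13 libraries on its high side, touched at least 3 groups and held the most genes, with at least 20, was kept as a candidate batch. This rule was written after the split had been noticed, and no label records a batch. The fit with a batch term was tested on simulated data with 10% of 50000 genes changed 2-fold or 4-fold in 1 batch. It called 0.0960% and 5.99% of the genes there, and 0% in simulated data without a change. A non-negative least squares mixture described the mean relative abundances of all genes in each rhizosphere with decaying root as a weighted sum of those in the detritusphere, both crops without decaying root and bulk soil. Alternatives fixed before the data were examined were quantile normalization, other filters, a larger pseudocount, fits with the compared libraries alone, a replicate block, other distances and leaving out each library. Fits without scaling, with median-ratio scaling, on thinned scores, and with or within the candidate batch were added after seeing the data. No library pair held identical values (0 pairs), and correlations of log2(scaled score + 1) over the tested genes were 0.604 to 0.833 within groups and -0.127 to 0.596 between groups.

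Tools were R 4.3.3 with limma 3.58.1 and vegan 2.7.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.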

Results

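Metagenomic DNA from soil was sequenced in 18 libraries that fell into 6 groups of 3. Rhizosphere soil is the soil held by living roots, and it was taken from wheat and from chickpea. Each crop had been grown with or without decaying roots of an earlier plant in the soil. The fifth group was soil attached to the decaying roots, called the detritusphere, and the sixth was bulk soil away from roots. The series title asks whether a preceding root system shapes the microbial community around the roots of the next crop. The labels do not name the plant that left the decaying roots, and they do not say whether replicates came from separate pots. The p-values therefore measure the spread between these libraries only.

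Each library had a score for each of 18646664 genes of a common list. The deposited table identifies genes by running numbers and does not pair them with names, functions or organisms. Gene groups are therefore described here by where they were found. Library totals were 55.6 ± 0.926 M (mega) score units in bulk soil, 52.2 ± 1.74 M in wheat without decaying root and 50.7 ± 0.127 M in chickpea without it (SD, n = 3 each). They were 39.0 ± 3.65 M in wheat with decaying root, 37.6 ± 0.310 M in chickpea with it and 36.3 ± 1.33 M in the detritusphere (SD, n = 3 each). Rhizosphere totals were lower by 13.1 M on average with decaying root than without, a difference of -13.1 M (exact two-sided permutation test within crop, p = 0.005, the smallest p that its 400 labelings allow). Group and library total thus went together, and all abundances below were scaled to a common total of 45.3 M. The scaled abundance of a gene is given in those units.

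The communities separated by whether decaying root was present. Bray-Curtis distance runs from 0 for communities with equal abundances to 1 for communities with no gene in common. Libraries of 1 group lay 0.271 apart in bulk soil, 0.294 in wheat and 0.289 in chickpea without decaying root, 0.366 and 0.352 in the same crops with it, and 0.363 in the detritusphere (means of 3 pairs each). Bulk soil lay 0.610 from the detritusphere, 0.455 from wheat without decaying root and 0.446 from chickpea without it (means of 9 pairs each). Group accounted for 0.706 of the sum of squared distances (permutation test, F = 5.75, p = 1e-05, the smallest that the permutations drawn can give). Over the 12 rhizosphere libraries, decaying root accounted for 0.377 and crop for 0.161 (exact permutation tests within the other factor, p = 0.005 for each, the smallest of 400 labelings). The interaction of crop and decaying root took a further 0.145, which was not tested.

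**Figure D1:**
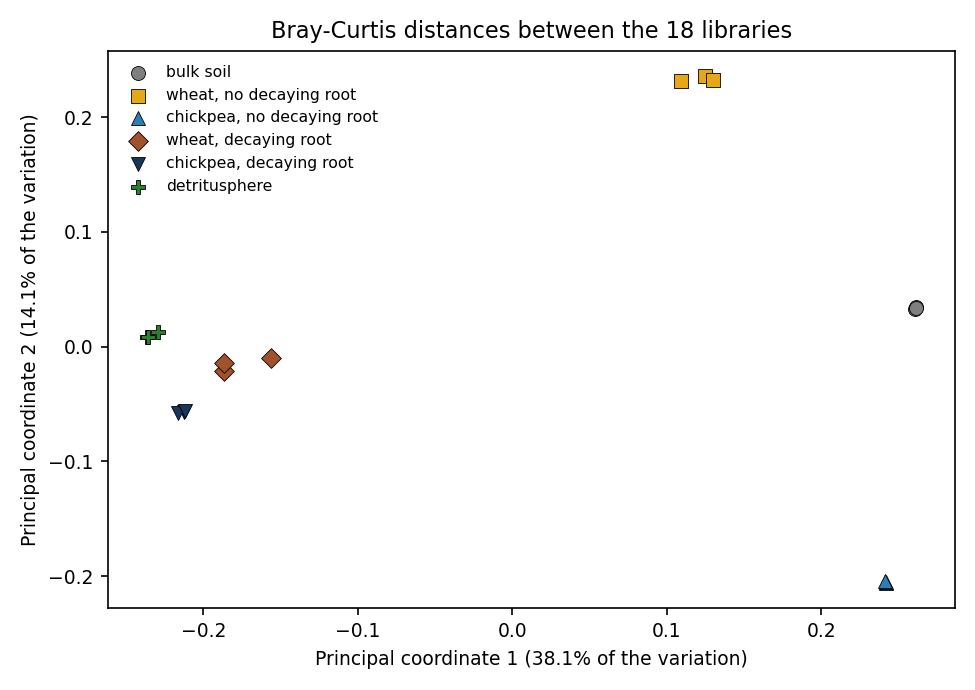
Principal coordinates of the Bray-Curtis distances between the 18 libraries, with the share of the variation on each axis (38.1% and 14.1%) and 1 point per library. The 9 libraries from soil with decaying root, detritusphere included, lie together on the left, whereas bulk soil and the rhizospheres of both crops without decaying root form 3 separate clusters on the right.

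The rhizosphere of either crop lay nearer to the detritusphere when decaying root was present. Wheat lay 0.539 ± 0.00460 from the detritusphere without decaying root and 0.395 ± 0.00328 with it (SD, n = 3 each). Chickpea lay 0.611 ± 0.000406 from it without decaying root and 0.409 ± 0.00134 with it (SD, n = 3 each). The mean fall in distance over both crops was 0.173 (exact two-sided permutation test within crop, p = 0.005, the smallest of 400 labelings). It was 0.144 in wheat and 0.202 in chickpea (exact permutation tests, p = 0.1 for each, the smallest that 3 libraries against 3 allow).

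Some of the 18 libraries shared a set of 37 genes that cut across the groups, and these libraries were treated as a candidate technical batch. The 37 genes made up 110 to 246 ppm of the library total in wheat with decaying root 2 and 3, wheat without decaying root 1 and all libraries of chickpea with decaying root and of the detritusphere. In the other 9 libraries they made up at most 0.284 ppm. The split was found in the data and is recorded in no label. The fall in distance to the detritusphere was 0.144 for the wheat libraries of the batch that lacked these genes and 0.140 for those of the batch that held them. All detritusphere libraries held the genes, so only the second value lies wholly within a batch. Both chickpea groups, bulk soil and the detritusphere each lay wholly in 1 batch. Chickpea with and without decaying root lay in different batches, as did the detritusphere and bulk soil, so no within-batch value can be given for these 2 comparisons.

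Wheat and chickpea rhizospheres were distinct without decaying root and drew close to each other with it. Their mean distance was 0.515 without decaying root (0.510 to 0.520 over 9 library pairs) and 0.391 with it (0.384 to 0.397). The difference of 0.123 exceeded the range over pairs (exact two-sided permutation test within crop, p = 0.005, the smallest of 400 labelings), and it was 0.123 over pairs from the same candidate batch. With decaying root the 2 crops lay a little farther from each other than libraries within 1 of these groups, which lay 0.366 apart in wheat and 0.352 in chickpea. The ranges did not overlap: the nearest pair across crops was 0.384 apart, and the farthest pair within a group 0.371 in wheat and 0.354 in chickpea.

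**Figure D2:**
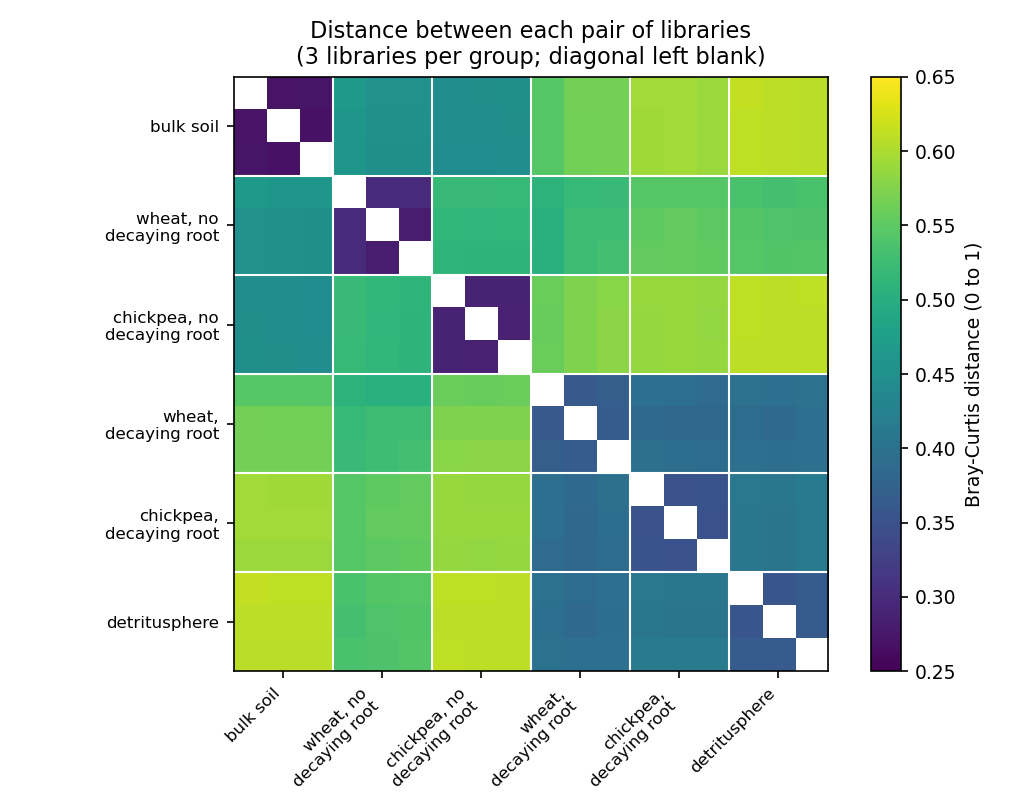
Bray-Curtis distance between each pair of the 18 libraries, from dark for near to bright for far, with 3 libraries per group and groups parted by white lines. The block of wheat with decaying root, chickpea with decaying root and detritusphere is dark throughout, with a mean distance of 0.391 between the crops, whereas wheat and chickpea without decaying root lie 0.515 apart.

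Rhizospheres with decaying root also held more genes than those without it. Genes detected per library were 10.3 ± 0.101 M in wheat without and 10.8 ± 0.424 M in wheat with decaying root, and 10.1 ± 0.0286 M in chickpea without and 10.4 ± 0.0224 M in chickpea with it (SD, n = 3 each). Bulk soil had 10.3 ± 0.0574 M and the detritusphere 10.3 ± 0.141 M (SD, n = 3 each). The rhizospheres gained 0.399 M genes on average (exact two-sided permutation test within crop, p = 0.005, the smallest of 400 labelings), in spite of their lower totals. After every library had been thinned to the lowest total the gain was 1.28 M (same exact permutation test, p = 0.005). Bulk soil then had 8.98 ± 0.00872 M genes and the detritusphere 10.2 ± 0.0195 M (SD, n = 3 each). The Shannon index of gene diversity was higher with decaying root by 0.223 on average (same exact permutation test, p = 0.005). For single pairs of groups the exact test cannot give a p below 0.1.

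Wheat rhizospheres with and without decaying root differed in a large share of the tested genes. Of 2070450 genes tested, 370877 were more abundant and 388011 less abundant in wheat with decaying root than without (limma, adjusted p under 0.05), 36.7% in all. The median size of a called change was 1.90 on the log2 scale. Gene total_2314637 was listed at 0 in all 3 wheat libraries without decaying root and reached 118 ± 27.0 with it (SD, n = 3; limma adjusted p = 5.39e-10). Its level in the detritusphere was 96.1 ± 10.4 (SD, n = 3). Gene total_10502522 was likewise listed at 0 in wheat without decaying root and reached 115 ± 37.3 with it (SD, n = 3; limma adjusted p = 2.43e-09). In the other direction, total_9011934 stood at 534 ± 38.4 in wheat without decaying root and was listed at 0 in all 15 other libraries (SD, n = 3; limma adjusted p = 1.78e-10). Gene total_9515918 stood at 328 ± 131 without decaying root and was listed at 0 in all 3 wheat libraries with it (SD, n = 3; limma adjusted p = 1.01e-06). The comparison gave 357159 genes within the candidate batch that lacked the shared genes and 361660 within the batch that held them, each resting on 1 library of 1 group. The changes of all tested genes in the 2 batches, which share no library, correlated with r = 0.743.

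Chickpea rhizospheres with and without decaying root also differed in many genes. With decaying root 505709 genes were more abundant and 467349 less abundant than without (limma, adjusted p under 0.05), 47.0% of the genes tested. The 10 genes with the largest rise all belonged to the 37 genes of the candidate batch. The first of them, total_3369535, was at 738, 847 and 329 in the 3 chickpea libraries with decaying root and listed at 0 in the 3 without (limma adjusted p = 0.00114), but it was also at 655 in wheat without decaying root 1. With a batch term its change was 0.27 on the log2 scale (limma adjusted p = 0.690). The batch was defined by where the 37 genes were high, so this loss of the change followed from that choice. The gene with the largest rise outside that set, chosen after its values had been seen, was total_373761, listed at 0 in chickpea without decaying root and at 162 ± 11.3 with it (SD, n = 3; limma adjusted p = 6.45e-11). Its level was 55.2 ± 9.28 in the detritusphere (SD, n = 3). Among genes that fell, total_6390918 was at 1279 ± 118 in chickpea without decaying root (SD, n = 3) and at 1.19, 0 and 1.21 with it (log2 change -9.56 ± 0.39 SE, limma adjusted p = 1.26e-10). Gene total_7640139 was at 737 ± 41.1 in chickpea without decaying root (SD, n = 3), and it was listed at 0 in all 9 libraries from soil with decaying root (limma adjusted p = 4.43e-11). The fit with a batch term called 569429 genes instead of 973058 in chickpea and 687978 instead of 758888 in wheat, so which crop had more called genes depended on that term. In chickpea 99.8% of the called changes kept their sign in that fit, their median size went from 2.03 to 1.96, and the median standard error was 1.47 times as large.

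Averaged over both crops, 537224 genes were more abundant and 571317 less abundant with decaying root (limma, adjusted p under 0.05), 53.5% of the genes tested. Gene total_12928546 rose from 1.17 ± 0.549 to 204 ± 34.9 in wheat and from 2.38 ± 1.03 to 403 ± 108 in chickpea (SD, n = 3 each; mean log2 change 6.74 ± 0.19 SE, limma adjusted p = 3.76e-12). Gene total_1025446 rose from 1.75 ± 0.924 to 249 ± 19.6 in wheat and from 1.49 ± 0.514 to 191 ± 28.9 in chickpea (SD, n = 3 each; 6.42 ± 0.18 SE, limma adjusted p = 3.76e-12). Both were also at over 200 in the detritusphere, with 208 ± 47.4 and 259 ± 60.4 (SD, n = 3 each). Gene total_9198439 fell from 98.8 ± 19.6 to 5.68 ± 2.75 in wheat and from 1678 ± 248 to 2.01 ± 0.708 in chickpea (SD, n = 3 each; -6.57 ± 0.21 SE, limma adjusted p = 7.28e-12). Gene total_14667402 was at 494 ± 127 in wheat and 74.4 ± 4.02 in chickpea without decaying root (SD, n = 3 each), at 0, 3.60 and 3.75 in wheat with it, and listed at 0 in chickpea with it (limma adjusted p = 1.36e-09). The gene sets of both crops overlapped: 231664 genes rose in both, where independent lists would share 90587, and 181856 fell in both, where independent lists would share 87583. Genes that rose in 1 crop and fell in the other numbered 18651 and 22401, against 83716 and 94772 for independent lists. The libraries of both comparisons were separate, but genes are not independent of each other, so no p is given for these overlaps.

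**Figure D3:**
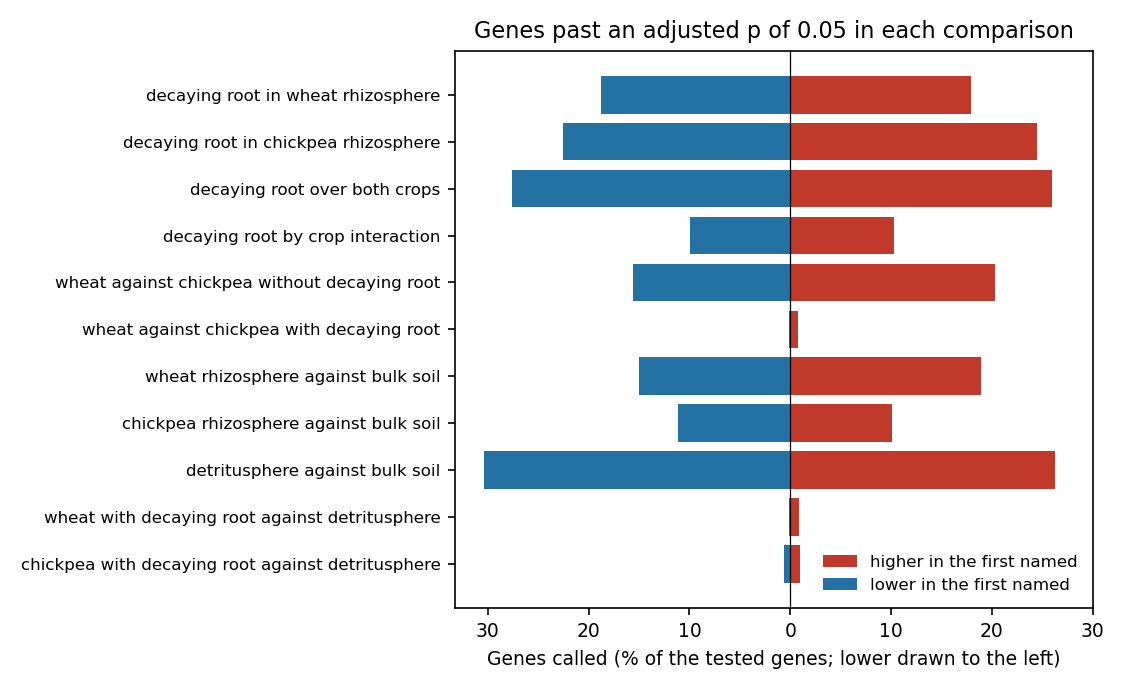
Share of the 2070450 tested genes that passed an adjusted p of 0.05 in each of the 11 comparisons, with genes higher in the first named group (with decaying root where only that is named, and changed more upward in wheat for the interaction) to the right and lower genes to the left. The 3 comparisons among groups with decaying root span 0.902% to 1.51% of the genes, and the other 8 span 20.2% to 56.6%.

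Many genes were called as changing differently with decaying root in wheat and in chickpea. The difference between the wheat change and the chickpea change passed an adjusted p of 0.05 for 418185 genes (limma), 20.2% of those tested, with 213200 changed more upward in wheat and 204985 more upward in chickpea. That balance moved with the scaling. Of 100 splits of the 12 rhizosphere libraries, 5 gave as many genes, the real one included, so this count does not exclude chance. Among the 5, 1 turned the decaying root labels of 1 crop, and without it 4 of 99 gave as many. Relabeling libraries within a crop can turn part of the shared change into an interaction, so neither count can decide this. Gene total_6390918, which fell in chickpea, was listed at 0 in wheat without decaying root and at most at 1.20 with it (limma adjusted p of the difference = 2.42e-08). Gene total_4197584 was at 484, 243 and 364 in chickpea without decaying root and listed at 0 in chickpea with it, while wheat had 15.7, 0 and 0 with decaying root and was listed at 0 without it (limma adjusted p = 3.39e-06). Gene total_9011934, which was found in wheat without decaying root alone, differed in the other direction (limma adjusted p = 8.20e-09). Gene total_10994831 was at 24.9 ± 15.1 in wheat without decaying root and 30.4 ± 14.8 in chickpea with it (SD, n = 3 each), was at 22.9 ± 8.03 in the detritusphere (SD, n = 3), was listed at 0 in wheat with it, and was at 0.894, 0.890 and 0 in chickpea without it (limma adjusted p = 9.09e-07).

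Without decaying root, the rhizospheres of the 2 crops differed in 742731 genes (limma, adjusted p under 0.05), 35.9% of those tested, with 420019 more abundant in wheat and 322712 in chickpea. Gene total_12657164 was at 707 ± 284 in wheat without decaying root (SD, n = 3), and it was listed at 0 in chickpea without decaying root and in bulk soil (limma adjusted p = 9.30e-09). It stayed at 361 ± 141 in wheat with decaying root (SD, n = 3). In both wheat groups it was higher in the libraries of the candidate batch, with 1035 against 533 and 554 without decaying root and 390 and 486 against 208 with it. Gene total_1058977 was at 4265 ± 418 in chickpea and 2.58 ± 1.43 in wheat without decaying root (SD, n = 3 each; log2 difference -10.28 ± 0.86 SE, limma adjusted p = 6.61e-08). It was at 5087 ± 1185 in chickpea with decaying root (SD, n = 3). With median-ratio scaling instead of the common total, the share of these genes that was more abundant in wheat went from 56.6% to 42.5%, so which crop had more of the called genes depended on the scaling.

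With decaying root, the crops differed in 18682 genes (limma, adjusted p under 0.05), 0.902% of those tested, 15209 of them more abundant in wheat and 3473 in chickpea. Gene total_1855534 was at 292 ± 141 in wheat with decaying root (SD, n = 3), against 0, 3.62 and 0 in chickpea with it (log2 difference 7.33 ± 0.56 SE, limma adjusted p = 1.23e-06). Gene total_583898 was at 5296 ± 1420 in chickpea with decaying root (SD, n = 3), against 5.24, 0 and 6.25 in wheat with it (-10.50 ± 0.85 SE, limma adjusted p = 2.14e-06). With a pseudocount 10 times larger the share that was more abundant in wheat fell from 81.4% to 49.1%, so the balance depended on that choice. The count depended on which libraries were fitted. With the 6 libraries of the comparison alone limma called 191 genes, and total_1855534 then had an adjusted p of 0.0574. Of the 420019 genes more abundant in wheat without decaying root, 5880 were also more abundant in wheat with it, where independent lists would share 3085. Opposite overlaps were also above that level in 1 direction: 4154 genes were more abundant in chickpea without and in wheat with decaying root, where independent lists would share 2371. The other opposite set had 546, where independent lists would share 705. Of the 322712 genes more abundant in chickpea without it, 837 were more abundant in chickpea with it, where independent lists would share 541.

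**Figure D4:**
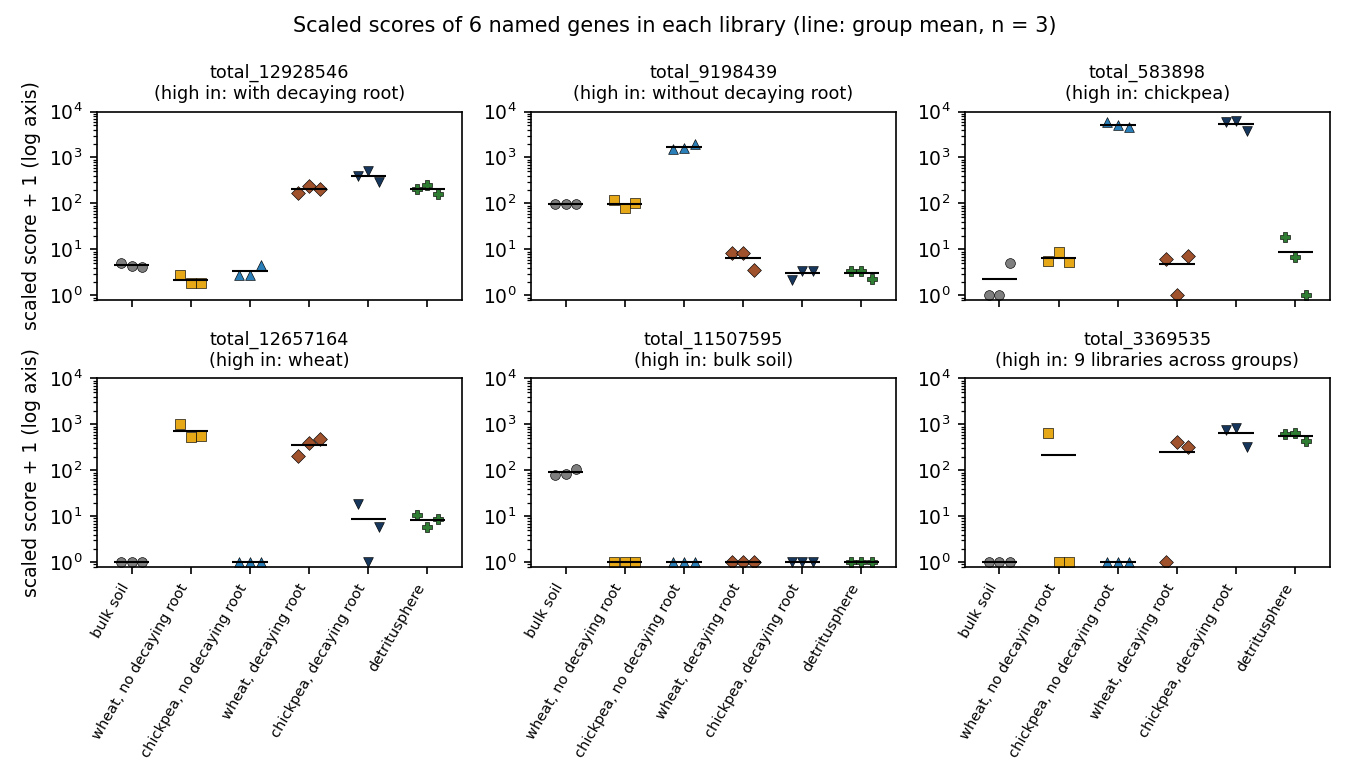
Scaled abundance plus 1 of 6 named genes in the 18 libraries, on a log axis, with 1 point per library and a line at the group mean (n = 3). The genes are, from left to right and top to bottom, high with decaying root, without it, in chickpea, in wheat, in bulk soil and in the 9 libraries of the candidate batch, where total_3369535 is at 655 in 1 wheat library without decaying root and at 0 in the others of that group.

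Rhizospheres without decaying root also differed from bulk soil. Wheat without decaying root differed from bulk soil in 700377 genes (limma, adjusted p under 0.05), 33.8% of those tested, with 390866 more and 309511 less abundant in the rhizosphere. Gene total_7098687 was at 793 ± 298 in wheat (SD, n = 3) and at 0, 0 and 0.799 in bulk soil (log2 change 9.29 ± 0.39 SE, limma adjusted p = 6.05e-10). Gene total_11507595 was at 89.6 ± 13.8 in bulk soil (SD, n = 3) and listed at 0 in all 15 other libraries (limma adjusted p = 6.58e-10). Chickpea differed from bulk soil in 438932 genes (limma, adjusted p under 0.05), 21.2% of those tested, with 208459 more and 230473 less abundant in the rhizosphere. Gene total_583898 was at 5189 ± 595 in chickpea without decaying root (SD, n = 3) and at 0, 0 and 3.99 in bulk soil (log2 change 11.56 ± 0.85 SE, limma adjusted p = 5.20e-08). Gene total_18358346 was at 272 ± 5.88 in bulk soil (SD, n = 3) and at 0, 0 and 0.893 in chickpea (-7.79 ± 0.45 SE, limma adjusted p = 3.08e-09). Median-ratio scaling moved the higher share in chickpea from 47.5% to 60.2%, so the balance of rises and falls there depended on the scaling.

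The detritusphere differed widely from bulk soil. It differed in 1172450 genes (limma, adjusted p under 0.05), 56.6% of those tested, with 542859 more and 629591 less abundant in the detritusphere. The 10 genes with the largest rise were again all among the 37 genes of the candidate batch. With a batch term the change of total_3369535 was 0.19 on the log2 scale (limma adjusted p = 0.766), which again followed from how the batch was defined. The gene with the largest rise outside that set, chosen after its values had been seen, was total_6185159, at 267 ± 27.6 in the detritusphere (SD, n = 3) and at 0.825, 0 and 0 in bulk soil (7.77 ± 0.33 SE, limma adjusted p = 1.26e-09). It was at 260 ± 62.6 in wheat with decaying root (SD, n = 3). Gene total_9831530 was at 384 ± 116 in bulk soil (SD, n = 3) and at 2.49, 0 and 0 in the detritusphere (-7.95 ± 0.67 SE, limma adjusted p = 1.15e-07). The fit with a batch term called 737507 genes. In it 99.8% of the called changes kept their sign, their median size went from 2.06 to 2.00, and the median standard error was 1.47 times as large. Without scaling between libraries the higher share of called genes fell from 46.3% to 31.2%, and it also fell from 48.9% to 32.1% for decaying root in wheat and from 52.0% to 37.8% in chickpea.

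Genes that rose in the detritusphere tended to rise in rhizospheres with decaying root. Of the 542859 genes higher in the detritusphere than in bulk soil, 38.8% were also higher with decaying root in wheat and 62.3% in chickpea, where independent lists would give 17.9% and 24.4%. Of the 629591 lower genes, 36.0% were also lower in wheat and 54.1% in chickpea, against 18.7% and 22.6%. Across the 2070450 tested genes, which are not independent replicates, the log2 changes with decaying root correlated with those of the detritusphere with Pearson r = 0.501 and Spearman rho = 0.477 in wheat and r = 0.686 and rho = 0.707 in chickpea. No library entered both sides of a correlation. In chickpea, however, both sides compared the candidate batch that held the shared genes with the batch that lacked them. A batch effect could therefore enter both sides there, and the chickpea overlaps too. Exact permutation of the decaying root labels within a crop gave p = 0.1 for each, the smallest that 20 labelings allow, and the highest r of the other labelings in absolute value was 0.394 in wheat and 0.524 in chickpea. For the mean over both crops, r was 0.594 and rho 0.592 (exact permutation test, p = 0.005 for both, the smallest of 400 labelings). In wheat r was 0.457 with wheat libraries of the candidate batch that lacked the shared genes and 0.452 with those of the batch that held them. The detritusphere change compared different batches in both values.

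**Figure D5:**
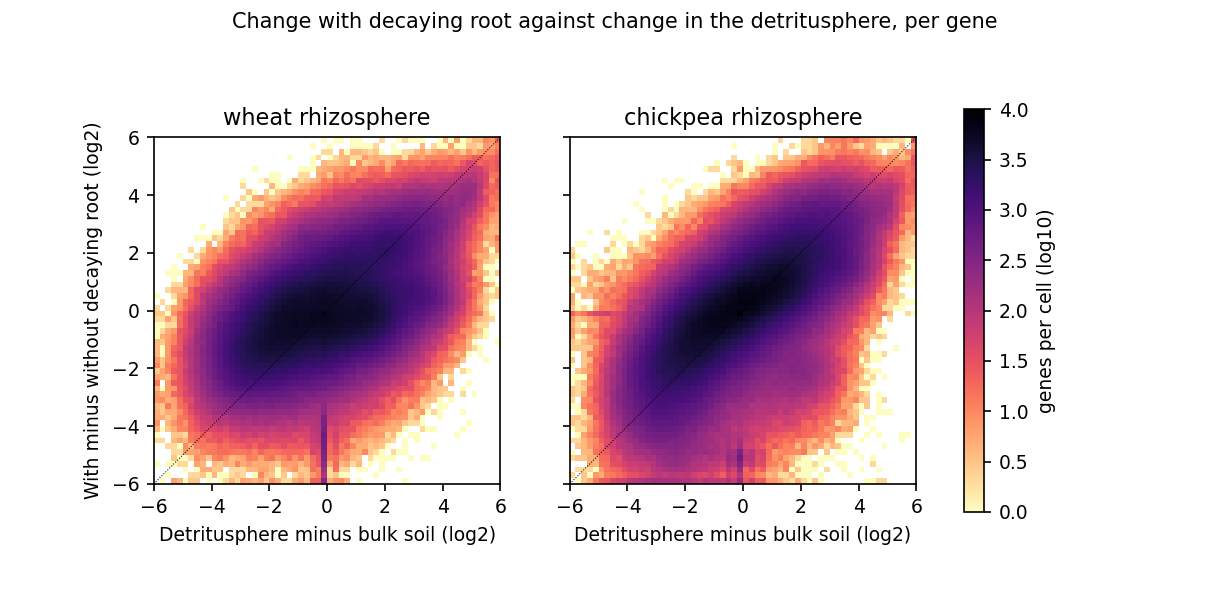
Log2 change of each tested gene with decaying root (vertical) against its log2 change in the detritusphere (horizontal), for wheat and chickpea, shaded by the log10 number of genes per cell, with changes beyond the axes drawn in the edge cells and a dotted line where both are equal. The cloud is elongated along that line in both crops, with r = 0.501 in wheat and r = 0.686 in chickpea.

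Few genes were called between rhizospheres with decaying root and the detritusphere itself. Wheat with decaying root differed from the detritusphere in 21696 genes (limma, adjusted p under 0.05), 18890 of them more abundant in wheat. Gene total_13386452 was at 339 ± 146 in wheat with decaying root (SD, n = 3) and at 2.49, 0 and 0 in the detritusphere (log2 difference 7.69 ± 0.52 SE). Gene total_11304654 was at 223 ± 99.4 in wheat with decaying root (SD, n = 3) and listed at 0 in the detritusphere (limma adjusted p = 2.04e-06). Gene total_14323904 was at 79.2 ± 6.47 in the detritusphere (SD, n = 3) and at 2.10, 0 and 0 in wheat with decaying root (-5.78 ± 0.41 SE, limma adjusted p = 1.01e-06). Chickpea with decaying root differed from the detritusphere in 31283 genes (limma, adjusted p under 0.05), 1.51% of those tested, with 19361 more and 11922 less abundant in chickpea. Gene total_5928507 was at 2845 ± 719 in chickpea with decaying root (SD, n = 3) and at 0, 6.02 and 0 in the detritusphere (10.50 ± 0.76 SE, limma adjusted p = 1.16e-06). Gene total_14323904 was listed at 0 in chickpea with decaying root (limma adjusted p = 3.07e-07). With only the 6 libraries of each comparison limma called 452 genes for wheat and 33 for chickpea, so these counts depended on which libraries were fitted. They also moved with 1 library: the wheat count was 13769 without wheat with decaying root 1 and 14045 without 2, and the chickpea count was 16657, 17051 and 16844 without chickpea with decaying root 1, 2 and 3. Leaving out 1 of these also turned the balance in chickpea, with the higher share falling from 61.9% to between 42.4% and 43.9%. The larger pseudocount moved the higher share in wheat from 87.1% to 62.7%, and without a filter on low genes it was 38.5%, so these balances depended on the settings.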

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

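The results in this part were picked out because a test of the difference itself found unlike changes with decaying root in wheat and chickpea. The test of the candidate batch was chosen after the result was seen. For the other tests the deciding value had not been computed when they were written, though related values had been seen.

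The change with decaying root differed between the crops for 418185 genes. On the log2(value + 1) scale the fitted difference, wheat change minus chickpea change, was 10.28 for total_6390918 and 9.81 for total_4197584, genes that were most abundant in chickpea without decaying root. It was -9.06 for total_9011934, found in wheat without decaying root alone. For total_10994831, most abundant in wheat without decaying root, in chickpea with it and in the detritusphere, it was -8.79. Groups listed at 0 enter these fits, so the values are no bound on the change. Of 100 splits of the 12 rhizosphere libraries, 5 gave as many genes for the interaction, the real one included, so chance was not excluded by this count. One of the 5 turns the labels of decaying root in 1 crop, which makes the shared change an interaction by construction, and without it 4 of 99 splits gave as many. Per 100000 genes the real split gave 20239 and the highest other 53653. That highest split is the turned one, and the highest of the remaining splits gave 30063. Relabeling only some libraries of a crop can likewise turn part of the shared change into an interaction. The count with or without the turned split therefore cannot decide on chance, and the 3 other splits with as many genes were not examined further.

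The interaction went with rhizospheres of wheat and chickpea that were near-alike with decaying root and distinct without it. The gap in distance, without minus with decaying root, was 0.123 before and 0.139 after thinning (0.136 to 0.141 when each library was left out). Thinning removes most units from the deeper libraries, those without decaying root, and the distances between them rose with it. The gap could thus hardly have closed, so this test cannot decide on lower library totals as a cause. A larger spread between libraries does not account for the near-alike rhizospheres as the whole cause. The variance of the crop difference, less replicate noise, was 0.0967 times as large with decaying root as without (0.0921 to 0.101). The candidate batch is argued against by pairs from the same batch without decaying root, which lay farther apart by 0.119 than pairs from different batches with it (at least 0.114). The different-batch pairs were 3, and all rest on 1 wheat library, wheat with decaying root 1. In a mixture of possible sources the detritusphere took a weight of 0.767 in wheat with decaying root and 0.813 in chickpea with it (0.740 to 0.817 over libraries), which is consistent with a community of the decaying root shared by both rhizospheres. The mixture described 0.742 of the variance over genes in the mean of wheat and 0.613 in that of chickpea (0.521 to 0.641 over libraries). Chickpea with decaying root and the detritusphere also lay wholly in the same candidate batch. A shared community stays a hypothesis, found and tested on the same libraries, and a difference in how soil with decaying root was sampled was not tested.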

How the results depend on the processing

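The fits without scaling, with median-ratio scaling, on thinned scores and with, within or across the candidate batch were chosen after the data were seen, and the other alternatives before the data were examined. No named gene and no community value changed direction (0 reversed), but the balance of rises and falls among called genes did in several comparisons. Of 78 gene counts with 1 library left out, 73 stayed within 1.5 times the main count and 5 fell below it, and of 127 under other alternatives 91 stayed, 22 fell and 14 rose. All 324 values of named genes with 1 library left out and 479 of 487 others kept their direction and side of the threshold. Of the community, agreement and richness values, all 135 with 1 library left out and 30 of 33 others were kept, and 3 within-batch values in wheat moved. The 135 include 12 for the agreement in wheat and 12 for that in chickpea. Their exact p cannot fall below 0.1, so these could change only by a turned sign.

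With 1 library left out, counts ran from 621065 to 685563 for decaying root in wheat, 855426 to 880515 in chickpea, 1033999 to 1078521 for both crops and 346372 to 381933 for the interaction. They ran from 600066 to 612939 for the crops without and 12997 to 18741 with decaying root, 558523 to 575130 for wheat and 318260 to 337995 for chickpea against bulk soil, and 1045293 to 1083948 for the detritusphere. Against the detritusphere they ran from 13769 to 23845 for wheat and 16657 to 24317 for chickpea with decaying root, where the higher share fell from 61.9% to as low as 42.4%. The cause was not tested.

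Without a filter 18646664 genes were tested, and the counts rose to 2253907 for decaying root in wheat, 3481130 in chickpea, 4594200 for both crops and 1090165 for the interaction. They rose to 2224054 for the crops without and 148168 with decaying root, 1304238 for wheat and 1355576 for chickpea against bulk soil, and 4484110 for the detritusphere. Against the detritusphere they rose to 201502 for wheat and 368369 for chickpea. Of the genes of the main fit, 1229734 were above 0 in all libraries. With these alone counts fell to 483133, 560030 and 633491 for decaying root in wheat, chickpea and both. They fell to 4595 for the crops with decaying root, 695466 for the detritusphere and 9872 for wheat against it.

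The crops with decaying root, and wheat and chickpea against the detritusphere, moved most: to 48083, 34007 and 95777 with a pseudocount 10 times larger, to 10408, 10902 and 9658 after thinning, and to 191, 452 and 33 with only the compared libraries. In that last fit 4 named genes also left the threshold (limma adjusted p 0.0574 to 0.0608). Libraries with decaying root and of the detritusphere deviated from their group mean by 0.592 to 0.634 (root mean square, log2). Those of the other groups deviated by 0.464 to 0.520. The fit of all libraries pools these spreads, and whether this caused the moves was not tested. A batch term gave 569429 for decaying root in chickpea, 12443 for the crops with it, 737507 for the detritusphere and 14316 for wheat against it. It also ended the calls of 4 named values, all of genes that define the batch. Leaving out both libraries that cross the batch gave 11782 for the crops with decaying root and 12751 for wheat against the detritusphere. Within the batch without the shared genes decaying root in wheat gave 357159 and an agreement r of 0.457. Within the other it gave 361660 and 0.452, with 11651 for the crops, 12507 for wheat against the detritusphere and a fall in distance of 0.140. These fits rest on fewer libraries, and a lone library was assumed to vary like the other groups.

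The balance of rises and falls depended on scaling, pseudocount and filter. The share of called genes that was higher went, without scaling, from 48.9% to 32.1% for decaying root in wheat, 52.0% to 37.8% in chickpea, 48.5% to 32.8% for both and 46.3% to 31.2% for the detritusphere. With median ratios it went from 51.0% to 62.5% for the interaction, 56.6% to 42.5% for the crops without decaying root and 47.5% to 60.2% for chickpea against bulk soil. With quantile normalization it went from 81.4% to 70.7% for the crops with decaying root and 87.1% to 72.9% for wheat against the detritusphere. The larger pseudocount gave 49.1% and 62.7% for these, and no filter gave 50.0% and 38.5%, with 42.5% instead of 61.9% for chickpea against the detritusphere and 43.6% for the crops without decaying root. Balances near 50% also turned elsewhere. Under the main scaling the median log2 change over tested genes was -0.14 for decaying root in wheat, -0.16 for the interaction, 0.22 for the crops without decaying root, -0.12 for chickpea against bulk soil, -0.14 for the detritusphere and 0.12 for wheat against it.

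Replicate numbers did not pair the libraries: same-number correlations of deviations from group means were -0.0969 to 0.0158, and 2 of 18 libraries matched their own number best. A replicate block kept all counts within 1.5 times the main ones, and moved most 31283 to 21917 for chickpea and 21696 to 16886 for wheat against the detritusphere and 18682 to 14755 for the crops with decaying root. Not run were the count model of DESeq2, as the scores are not counts, and the genus level, the fixed lists and the removal of eukaryotic genes, as the genes have no names or taxa. Bray-Curtis distance on genes as listed was already the main choice.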

Other observations

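The tests in this part that were chosen after the result was seen are the swap of labels, the simulated batch change, the counts of genes by presence and the profiles of crop genes, also by batch.

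Many genes were detected in whole groups of libraries and nowhere else. Genes above 0 in all 9 libraries from soil with decaying root and listed at 0 in all others numbered 120913, the most of the 48620 sets of 9 libraries. The next set, bulk soil and both rhizospheres without decaying root, had 24734, and the median set had 12. After thinning the numbers were 124239 and 10976. Chickpea without decaying root had 94345 genes of its own, against 18682 in bulk soil, 14233 in wheat without decaying root, 12420 in the detritusphere, 8088 in wheat with decaying root and 6970 in chickpea with it. Of 17352 genes that split the libraries cleanly into high and low, 15381 (88.6%) followed whole groups. Chickpea without decaying root alone was high for 8071 of them and wheat without decaying root alone for 5555.

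Some genes marked the crop whether or not decaying root was present. In the 664 genes high in both wheat groups alone, the summed share was 2413 ± 900 ppm of the library total in wheat without decaying root and 1289 ± 506 with it (SD, n = 3 each), and 647 of them were lower with decaying root. Their share also moved with the candidate batch, and 647 of the 664 were higher in its libraries in both wheat groups. It was 3450 ppm in wheat without decaying root 1, which is in the batch, against 1940 and 1848 in 2 and 3, and 744 ppm in wheat with decaying root 1, which is not, against 1381 and 1742 in 2 and 3. Within either batch it was lower with decaying root. It was 23.6 ± 6.39 ppm in chickpea with decaying root and 19.3 ± 4.08 in the detritusphere (SD, n = 3 each). The 68 genes high in both chickpea groups alone summed to 409 ± 46.1 ppm without and 459 ± 110 with decaying root (SD, n = 3 each), and to at most 0.714 elsewhere. If each set came from 1 source of fixed gene ratios, the genes would correlate at 0.9 or more between all libraries of a crop. The lowest correlation was 0.867 in wheat and 0.944 in chickpea, so the test left open whether each crop had 1 source. No biological explanation was tested, since the genes have no names.

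The 37 genes of the candidate batch were present in 9 libraries that cross the wheat groups, and 32 of them were listed at 0 in all other libraries. Swapped labels of wheat with decaying root 1 and wheat without decaying root 1 are argued against, since both lay nearer to their own group, by 0.136 and 0.221 in Bray-Curtis distance. Genes outside the set also followed the split: the batch coefficient in limma passed an adjusted p of 0.05 for 159 genes (0.00768% of those tested), of which 122 were outside the set and 102 of these were higher in the wheat libraries of the batch, the only ones that inform this coefficient. The unadjusted share was 6.95% at p under 0.05. Simulated data without a batch change gave 0% and 4.91%, both below the values found. A simulated batch change in 10% of the genes gave 0.0960% and 8.80% when 2-fold, both above the values found. It gave an unadjusted share of 12.8% when 4-fold. Simulated settings set no bound on the real libraries, so how far a smaller or rarer batch effect reached stayed open. At equal replicate numbers, deviations from group means correlated at -0.0969, -0.0331 and -0.0505 between wheat with and without decaying root. Each of these library pairs joins different batches. All other group pairs lay between -0.0124 and 0.0158. The negative sign is the one a batch shift over many tested genes would give. Deviations within a group balance each other, so these values are not independent, and their size was not tested. A single added or contaminating source of fixed gene ratios would give a correlation of 0.9 or more between all 9 libraries. The lowest between 2 of them was 0.891, so this test left it open. The deposited scores argue against fixed ratios over all 37 genes. Genes total_5366930 to total_5366934 and total_12297812 to total_12297815 were lower in wheat without decaying root 1 than in wheat with decaying root 2. All were higher in chickpea with decaying root 3 than in 2. Most of the others went the opposite way in both pairs. Gene total_3369535 was at 727 against 344 and 272 against 701, total_5366934 at 62 against 101 and 90 against 68. No biological explanation was tested for these genes.

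The counts of called genes were set against other splits of the same libraries, each on 100000 genes. For decaying root averaged over both crops, 1 of 100 splits, the real one, gave as many genes. It called 53653 genes, against 27344 in the highest other split. The share is under the 0.05 set before and argues against a chance labeling of these libraries. It does not address the candidate batch, since chickpea with and without decaying root lay in different batches. For the comparisons of 2 groups, 1 of 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 36635 and 8 for decaying root in wheat, 46954 and 2 in chickpea, 35882 and 2 for the crops without decaying root and 898 and 18 with it. They were 33512 and 1 for wheat and 21324 and 1 for chickpea against bulk soil, and 56693 and 1 for the detritusphere. Against the detritusphere they were 1033 and 25 for wheat and 1675 and 31 for chickpea with decaying root. In wheat the split that follows the candidate batch gave 8 genes.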
